A study of Homo sapiens with 6 samples.

How the data were processed

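RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out in A549 cells, a human lung carcinoma line, with antibodies against 5 proteins that add or remove N6-methyladenosine (m6A) on RNA. METTL3, METTL14 and WTAP belong to the methyltransferase complex (writers), and ALKBH5 and FTO are demethylases (erasers). Per the labels' protocols, 5% of the lysate volume was kept as INPUT, and each pulldown used 5 µg of antibody on 50 µl of protein A/G beads with 100 µl of lysate for 4 h, followed by 5 washes. Libraries were made from total RNA with a stranded low-input kit, per the labels' protocols. The series was taken as 6 libraries, 1 INPUT and 1 immunoprecipitate (IP) per antibody, with no replicate library in any group. No IgG pulldown was among the libraries.

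The authors deposited 1 table of raw read counts per gene symbol, not normalised, with 56269 genes. The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 and the genome build hg38. Their versions and settings, the annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes, and of a gene and its antisense partner, were therefore treated as not separable, and genes with near-identical copies are named as uncertain. No row named a total or an unassigned class, and each of the 6 columns was matched to its sample by name. A table of RefSeq genes on GRCh38 (the same build as hg38) gave current symbols, biotypes and coordinates, which are 1-based. Of the 14029 genes analysed, 91.9% matched it, 721 of them through an older symbol. It holds genomic spans but no exons or sequences, so transcript length, exon structure and GC content were not analysed. Coordinates of mitochondrial genes are not given.

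Counts were normalised with TMM factors from edgeR 4.0.16 (INPUT as reference) in R 4.3.3. The log2 ratio of an IP to INPUT was computed from the counts divided by the effective library sizes, with 1 read added to each count. Genes with a mean CPM (depth-scaled count) of at least 1 over the 6 libraries were kept. A gene was called higher or lower when its ratio was at least 2-fold and the exact (Clopper-Pearson) 95% interval of the ratio of both counts excluded 1. These intervals cover counting error only, and PCR reads without molecular identifiers are not independent molecules. With 1 library per group no p-values were computed across genes, and every difference compares 2 libraries and has no replicate check. An IP-specific gene exceeded each other IP by the same rule. A gene separated writers from erasers when the lowest IP of 1 class lay at least 2-fold above the highest of the other, and all 10 splits of the 5 IPs into 3 and 2 were counted alike.

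Because all 5 IPs share 1 INPUT, 20 sets of Poisson counts were drawn with no effect against that INPUT, and the overlap of independent lists was computed beside them. Medians of 24 gene lists fixed before the data were examined, 1 of them markers of cell types that an A549 culture should lack, were ranked among 10000 random lists of the same size matched on mean CPM in 20 bins. These percentiles describe the 6 libraries.

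Named genes followed a rule fixed before the data were examined: mean CPM of at least 10 and a symbol that is not a clone name, and either 1 of the 10 highest or lowest ratios per IP, 1 of the 5 most IP-specific, 1 of the 5 largest writer or eraser gaps, 1 of the 10 most extreme in all 5 IPs, or 1 of the 5 most abundant per library. The 5 regulators, and for each list its 4 most abundant members and its 2 extremes, were named whatever their level. The rule gave 217 genes. Genes chosen after their values were seen are identified as such.

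The call rule was tested on simulated data drawn from the INPUT profile at the real library sizes. Of 200 genes changed by known folds among 14029, 100% (METTL3 IP), 98% (METTL14 IP), 99% (WTAP IP), 100% (ALKBH5 IP) and 98% (FTO IP) of those changed 4-fold were recovered, and 97%, 94%, 97%, 97% and 98% of those changed 3-fold.

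The alternatives fixed beforehand were DESeq2 1.42.0 size factors, plain totals, a CPM minimum of 5, no filter, 5 reads added, an interval bound past 2-fold, libraries thinned to the smallest total, removal of dominant genes, and the other IPs as comparator. Counts of protein-coding genes only, and counts without both shallow IPs, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.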

Results

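The 6 libraries held 26232039 counted reads for INPUT, 34580066 for the METTL3 IP, 10805682 for the METTL14 IP, 39004083 for the WTAP IP, 29105205 for the ALKBH5 IP and 9896797 for the FTO IP. The METTL14 and FTO IPs were thus the shallow libraries, with 19342 and 19592 genes detected against 25323 to 27069 in the other 4. A count of 0 allowed up to 0.278 CPM in the METTL14 IP and 0.303 CPM in the FTO IP, against 0.0769 CPM in the WTAP IP. The series was designed to find RNAs bound by the 5 m6A regulators in untreated A549 cells. There was 1 library per antibody, so each ratio below is given with its counting interval or as a count of genes, and no difference could be set against a spread between replicates.

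The mRNAs of the regulators themselves were read first. The METTL3 transcript (chromosome 14) was 2.52-fold above INPUT in the METTL3 IP and 1.11-fold above it in the FTO IP. The METTL14 transcript (chromosome 4) was highest in the METTL14 IP, at log2 1.91, followed by the WTAP IP at 1.04. The WTAP transcript had a log2 ratio of 0.52 in the WTAP IP and lay between -0.80 and -0.12 in the other 4. ALKBH5 mRNA stayed near INPUT in its own IP (0.08), and FTO mRNA reached 0.78 in both the FTO and the METTL14 IPs. By the 2-fold rule, METTL3 was higher in 1 IP, METTL14 in 2, and the other 3 transcripts in none. A pulled-down protein need not enrich its own mRNA, so these values check no label.

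**Figure D1:**
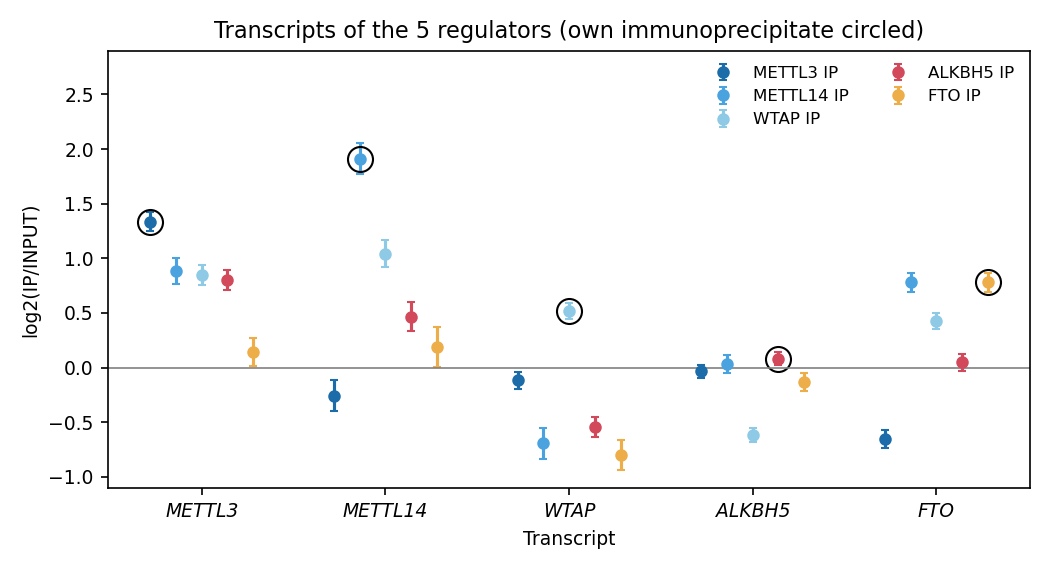
Log2 ratio to INPUT (vertical axis) of the 5 regulators' transcripts (horizontal axis) in each immunoprecipitate, 1 library each. Bars are exact 95% counting intervals and a circle marks the transcript's own immunoprecipitate, which held the highest value for METTL3 (1.34), METTL14 (1.91) and WTAP (0.52), while the intervals of FTO overlapped between the FTO and METTL14 immunoprecipitates.

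Against INPUT, the median log2 ratios of mitochondrial RNAs, small structured RNAs, histone mRNAs and ribosomal protein mRNAs lay below 0 in all 5 pulldowns, and that of very long coding mRNAs lay above 0. Of 14029 genes, 409 were higher and 903 lower in the METTL3 IP, 1545 and 1903 in the METTL14 IP, 1535 and 1874 in the WTAP IP, 2049 and 2630 in the ALKBH5 IP, and 1896 and 1949 in the FTO IP. Draws with no effect gave on average 12.6, 41.2, 13.9, 17.6 and 38.2 calls. The draws hold counting error alone, so they give no rate of false calls between libraries. Plain totals shifted the median log2 ratio of all genes by 0.19 in the METTL3 IP, -0.14 in the METTL14 IP, -0.15 in the WTAP IP, 0.02 in the ALKBH5 IP and 0.20 in the FTO IP. With that scaling the counts became 798 and 704 for METTL3, 1194 and 2368 for METTL14, 1126 and 2398 for WTAP, and 2522 and 1430 for FTO, so the share of higher genes went from 31.2% to 53.1%, 44.8% to 33.5%, 45.0% to 32.0% and 49.3% to 63.8%. Every ratio below is therefore relative to the bulk of transcripts in its library.

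**Figure D2:**
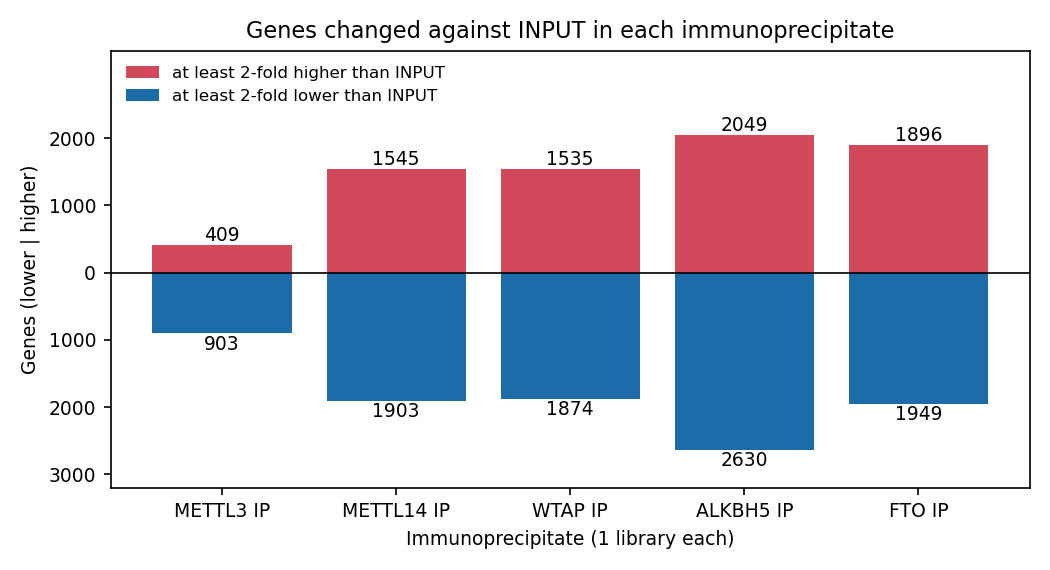
Numbers of genes at least 2-fold higher (upward bars) or lower (downward bars) than INPUT in each immunoprecipitate, out of 14029 genes. The METTL3 immunoprecipitate had the fewest (409 and 903) and the ALKBH5 immunoprecipitate the most (2049 and 2630).

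Mitochondrial and small structured RNAs took smaller shares of the reads in all 5 IPs than in INPUT. Mitochondrially encoded RNAs took 3.09% of the reads in INPUT and 0.123% in the METTL3 IP, 1.10% in the METTL14 IP, 0.116% in the WTAP IP, 0.196% in the ALKBH5 IP and 1.54% in the FTO IP. Small structured RNAs such as 7SL and 7SK went from 3.76% to 0.0290%, 0.469%, 0.101%, 0.177% and 0.535% in the same order, and of 16 measured members 16, 8, 12, 12 and 10 were lower. In the METTL14 and FTO IPs 2 members were higher, among them RNU12, a small nuclear RNA of the minor spliceosome (1.69 and 1.73). The widest exact (Clopper-Pearson) 95% interval of these shares was 1.53% to 1.55%, that of mitochondrial RNAs in the FTO IP. RN7SL1, the RNA of the signal recognition particle (chromosome 14, 49586580 to 49586878), fell by 9.18 on the log2 scale in the METTL3 IP and by 4.48 in the FTO IP, although its reads cannot be told apart from those of near-identical copies. RN7SK, which holds back transcription elongation factor P-TEFb, had log2 ratios from -6.60 (METTL3 IP) to -2.34 (FTO IP), and RPPH1, the RNA of RNase P, from -7.09 to -2.68. MT-RNR2, the large mitochondrial ribosomal RNA, was at -7.41 in the METTL3 IP and -1.22 in the FTO IP. MT-ND6, for which reads of either strand could not be told apart, had 0.34, -0.17, -1.38, -0.21 and 0.91.

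Replication-dependent histone mRNAs, which end in a stem-loop and lack a poly(A) tail, were lower for 55 of 55 measured genes in the METTL3 IP, 30 in the METTL14 IP, 47 in the WTAP IP, 53 in the ALKBH5 IP and 39 in the FTO IP. Their median log2 ratios were -3.77, -1.05, -2.28, -2.52 and -1.40. HIST1H3C, for example, was at -5.55 in the METTL3 IP and -2.21 in the FTO IP. Of 73 ribosomal protein genes, 27, 44, 53, 72 and 67 were lower, with medians of -0.84, -1.16, -1.45, -2.35 and -1.56, and RPS29 fell by 5.40 in the ALKBH5 IP while RPL3 had -0.48 there. Nuclear-encoded oxidative phosphorylation genes had medians of -0.93, -1.37, -2.11 and -1.46 in the METTL14, WTAP, ALKBH5 and FTO IPs, where 26, 37, 49 and 44 of 59 were lower. None of the 59 was lower in the METTL3 IP, whose median of -0.16 turned to 0.0220 with plain totals, a scaling that shifts all genes alike. That METTL3 median lay at percentile 0.14 of random lists. COX6C, a subunit of cytochrome c oxidase, had log2 ratios of -3.84 in the ALKBH5 IP and -0.54 in the METTL3 IP.

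Of 22 very long coding mRNAs, 22 were higher in the ALKBH5 IP, 20 in the METTL14 IP, 19 in the FTO IP, 11 in the WTAP IP and 1 in the METTL3 IP, and the medians were 2.04, 1.67, 1.67, 1.00 and 0.28. AHNAK2, which encodes a giant scaffold protein (chromosome 14, 104937253 to 104978374), had 2.75 in the ALKBH5 IP, and MDN1, a ribosome assembly ATPase, had 2.55 there and 2.39 in the FTO IP. ZNF genes, mostly transcription factors with a long last exon, shifted by 0.18, 0.23, 0.32 and 0.37 in the METTL14, WTAP, ALKBH5 and FTO IPs, each above all 10000 random lists. Their METTL3 IP median of -0.15, at percentile 0.01 of random lists, became 0.0346 with plain totals. Among the 329 ZNF genes, 5 to 59 were higher and 7 to 23 lower, so the shift was small for most members.

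**Figure D3:**
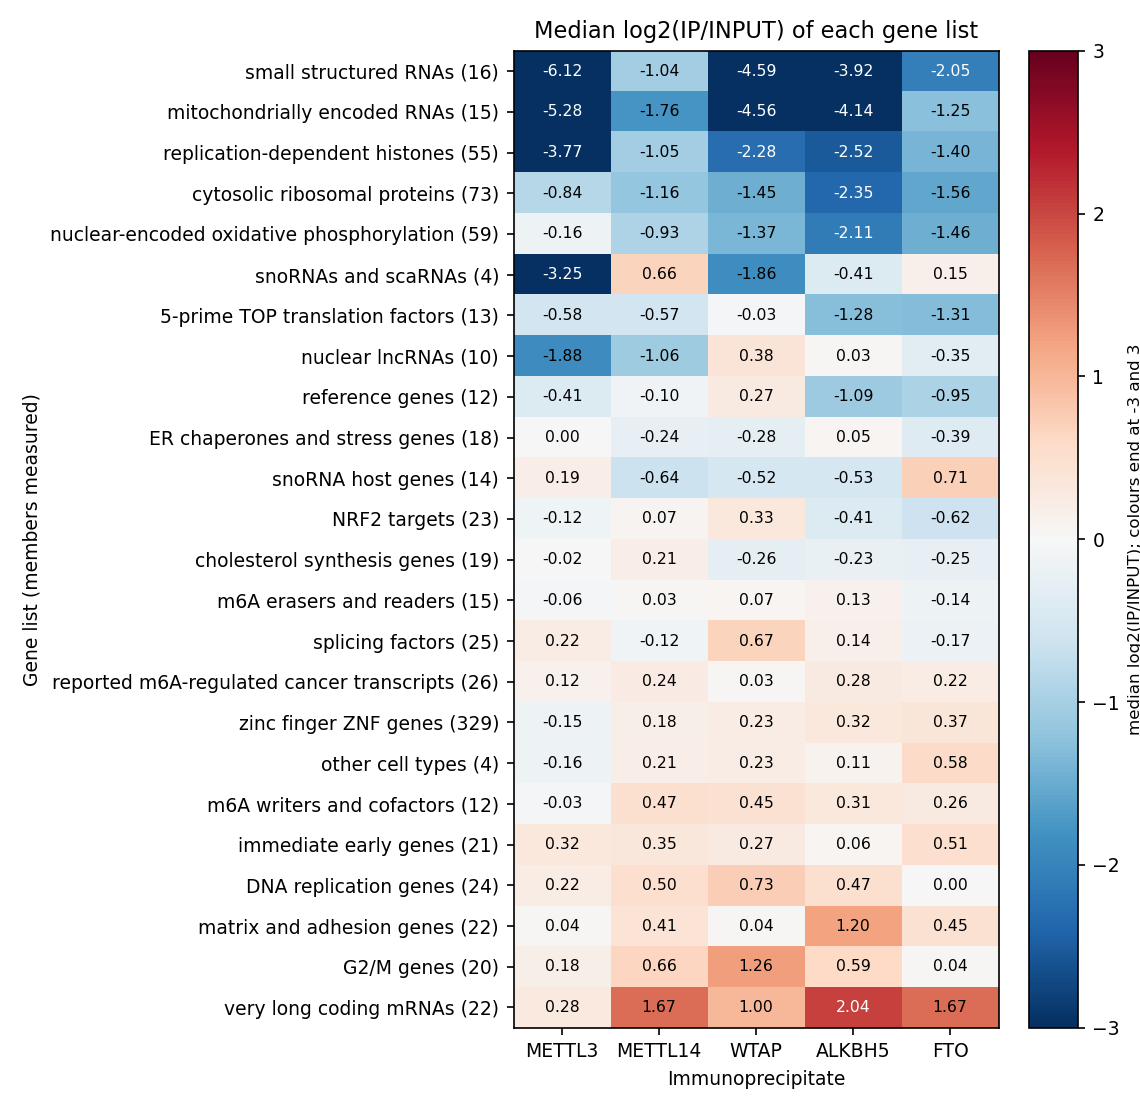
Median log2 ratio to INPUT of each gene list (rows, number of measured members in parentheses) in each immunoprecipitate (columns, 1 library each), with colours ending at -3 and 3. Small structured, mitochondrial and histone RNAs lay below 0 in all 5 columns, and very long coding mRNAs ranged from 0.28 (METTL3) to 2.04 (ALKBH5). With plain totals the METTL3 medians of the oxidative phosphorylation and ZNF lists turned positive.

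The METTL3 IP differed least from INPUT among mRNAs. Among its highest ratios were those of PABPC3 (2.36) and PABPC1 (1.83), cytoplasmic poly(A)-binding protein genes that share much of their sequence and so could share reads. NFKBIA, the inhibitor of NF-κB (chromosome 14, 35401513 to 35404749), had a log2 ratio of 1.93 with a counting interval of 1.87 to 2.00, and SRSF5, a splicing factor, had 1.76. The snoRNA host gene SNHG7 reached 1.77. Nuclear lncRNAs were depleted here, with 8 of 10 lower and a median of -1.88. MALAT1 was at -4.74 and NEAT1, the scaffold of paraspeckles, at -1.65.

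Several of the highest ratios in the METTL14 IP were those of cytoskeletal genes. ACTN4 and ACTN1, which encode actin-crosslinking α-actinins, had log2 ratios of 4.60 and 4.23, and ACTN4 (chromosome 19, 38647649 to 38731589) was the most abundant gene of this library with 135153 reads. MYH9 and MYH14, nonmuscle myosin heavy chains, had 4.22 and 3.51, MYO18A had 3.37, and FLNA, the actin crosslinker filamin A, had 3.71. ACTN4, MYH9 and FLNA were also higher in the ALKBH5 IP (1.64, 2.01 and 1.92) and the FTO IP (2.16, 2.06 and 1.66). TUBB and TUBB2A, β-tubulins, had 2.70 and 2.20, and TUBBP1, a tubulin pseudogene that could share their reads, had 4.80. Nuclear lncRNAs were lower for 6 of 10 genes, and snoRNA host genes for 6 of 14 (median -0.64).

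In the WTAP IP, 12 of 20 G2/M genes were higher, with a median of 1.26 that exceeded all 10000 random lists. TOP2A, the topoisomerase of mitotic chromosomes, had 2.16, CENPF 2.08 and MKI67 1.83. HSP90AA1 (1.92), HSP90AB1 (1.70) and HSP90B1 (1.81), which encode HSP90 chaperones, were higher, and 4 HSP90 pseudogenes, among them HSP90AA6P (3.45), ranked at the top but could share reads with the parent genes. The list of ER chaperones and stress genes, by contrast, had 2 of 18 higher, 4 lower and a median of -0.28. DNA replication genes had a median of 0.73 and 10 of 24 higher, MCM3 at 1.62 and MCM7 at 1.73. MALAT1, a lncRNA of nuclear speckles (chromosome 11, 65497738 to 65506516), was at 1.08, against -4.74 to -0.58 in the other 4 IPs, and 3 of 10 nuclear lncRNAs were higher. NCL, the nucleolar protein nucleolin, had 1.91. KIT, a receptor tyrosine kinase, had 652 reads here, 1 in INPUT and at most 6 in the METTL3, METTL14 and ALKBH5 IPs. Its WTAP IP to INPUT comparison gave a log2 ratio of 7.93 with an interval of 6.44 to 14.23.

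The ALKBH5 IP combined gains of long mRNAs with those of matrix genes. Of 22 matrix and adhesion genes 13 were higher, with a median of 1.20 above all random lists. LAMA5 and LAMB1, laminin chains of the basement membrane, had 2.10 and 1.31, and ITGB1, an integrin subunit, had -0.09. The highest single ratios were those of the Cajal body RNA SCARNA2 (3.68, from 67 reads in INPUT), and of NBPF20 (3.15), GOLGA8A (2.95) and HERC2P2 (2.80), members of segmentally duplicated families that could share reads. CELSR3, a cadherin of planar cell polarity, had 2.55.

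Among the highest ratios in the FTO IP was that of GADD45B, a growth arrest and DNA damage gene (chromosome 19, 2476127 to 2478257), at log2 4.72 with an interval of 4.58 to 4.87. DDIT3, the stress-induced transcription factor CHOP, had 3.54, TSC22D3, a glucocorticoid-induced gene, 3.35, and JUN, a subunit of AP-1, 3.21, whereas the list of ER chaperones and stress genes had 1 of 18 higher and 3 lower. Of 21 immediate early genes 6 were higher and none lower (median 0.51, percentile 99.1), KLF10 at 1.53 among them and DUSP1 at 0.34. snoRNA host genes had a median of 0.71 with 6 of 14 higher, SNHG12 at 2.18 and SNHG7 at 1.74. FGFR3, a fibroblast growth factor receptor (chromosome 4, 1793293 to 1808867), had 6.50, and KIT (chromosome 4, 54657957 to 54740715) had 599 reads and a ratio of 9.44 with an interval of 7.95 to 15.74. Of 23 NRF2 targets 7 were lower and 2 higher here, and 5 lower and 3 higher in the ALKBH5 IP, with medians of -0.62 and -0.41, AKR1B10 at -1.04 in the FTO IP.

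Messenger RNAs reported as m6A-regulated in cancer had medians of 0.12, 0.24, 0.03, 0.28 and 0.22 in the order METTL3, METTL14, WTAP, ALKBH5 and FTO, between percentiles 24.1 and 87.7 of random lists, and 1 to 4 of 26 genes were higher, while the WTAP median became -0.12 with plain totals. CTNNB1, which encodes β-catenin, was higher in 4 IPs (1.00 to 1.73) and had 0.48 in the FTO IP, and MYC was higher in the WTAP IP (1.23). The median of m6A writer and cofactor transcripts was at most 0.47 (METTL14 IP), with KIAA1429 (VIRMA) at 2.05 there, while its METTL3 value, slightly below 0, was above 0 with DESeq2 size factors and with plain totals. The median of eraser and reader transcripts lay between -0.14 and 0.13 and changed sign with plain totals in all IPs but that of ALKBH5, and with DESeq2 size factors in the METTL14 IP. ER chaperone and cholesterol synthesis genes had medians between -0.39 and 0.21, of which the METTL3 cholesterol median, slightly below 0, was above 0 with DESeq2 size factors and with plain totals. Non-ribosomal 5'TOP mRNAs were lower for 8 of 13 genes in both eraser IPs (medians -1.28 and -1.31), TPT1 being lower in all 5 (-3.24 to -1.68). Splicing factor mRNAs had a median of 0.67 in the WTAP IP (percentile 81.6 of random lists), HNRNPM at 1.68. Their median of -0.12 in the METTL14 IP was at percentile 0.7. Reference mRNAs were not constant, with medians of -1.09 and -0.95 in the ALKBH5 and FTO IPs and GAPDH at -1.48 and -1.30. The 4 measured snoRNAs and scaRNAs had a median of -3.25 in the METTL3 IP and 0.66 in the METTL14 IP. Of the 19 markers of other cell types, 4 reached the CPM minimum, with medians between -0.16 (METTL3 IP, 0.03 with plain totals) and 0.58 (FTO IP), and COL1A1, a fibrillar collagen, was highest at 1.63 in the METTL14 IP.

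Across all 5 antibodies, 29 genes were higher and 153 lower than INPUT. Draws with no effect, which hold counting error alone, gave 0.300 and 0 on average, and independent lists of these sizes would share 0.0973 and 0.426 genes. The higher set included PAN2, a poly(A) nuclease (1.22 to 2.27, chromosome 12, 56316936 to 56334000), TRIM25, an E3 ubiquitin ligase (1.25 to 1.44), NCDN (1.22 to 1.55), POLD1, the catalytic subunit of DNA polymerase δ (1.13 to 1.76), and TAF1, the scaffold of TFIID (1.06 to 1.93). The lower set included RN7SL1, RN7SK, RPPH1, VTRNA1-3, MT-ATP8, RPS29 and the mitochondrial tRNA gene MT-TV, which had 6433 reads in INPUT and 9 to 16 in the IPs. Ferritin mRNAs FTH1 and FTL were lower in all 5 as well (-2.57 to -1.17). Without the METTL14 and FTO IPs, a choice made after the data were seen, 66 genes were higher and 301 lower in the other 3, and among protein-coding genes alone 18 were higher and 80 lower in all 5. Part of these overlaps may come from the single shared INPUT, which could not be divided. Without an IgG library, RNA held by a protein and RNA held by any bead cannot be told apart for genes common to all 5 pulldowns.

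Each antibody also had genes of its own. The METTL3 IP exceeded each other IP at least 2-fold for 275 genes, the METTL14 IP for 228, the WTAP IP for 259, the ALKBH5 IP for 75 and the FTO IP for 458. For METTL3 these were led by mRNAs with log2 ratios to INPUT below 0 in each of the other 4 IPs. DNAJC19, a mitochondrial import factor, was 8.30-fold above the next IP but 0.95 (log2) above INPUT, and DDT, GLRX, RPS27L and CENPK were 4.01 to 4.58-fold above the next. For METTL14 the leading genes were TUBBP1 (7.64-fold), TUBB2A (5.48-fold), ACTN4 (5.43-fold), TUBB (5.18-fold) and ACTN1 (5.05-fold). SRR (3.42-fold), TPM2 (3.20-fold), MALAT1 (3.16-fold), XRCC2 (3.03-fold) and NCL (2.99-fold) led for WTAP. For FTO they were GADD45B (log2 3.91 over the next IP), FGFR3 (12.3-fold), RND1 (7.93-fold), PDRG1 (7.74-fold) and MED9 (7.16-fold). The ALKBH5 genes were closer to the FTO IP, with TTC13 (2.70-fold) and SLC12A9 (2.54-fold) among the first. With plain totals the METTL3 count became 479, the METTL14 count 146 and the WTAP count 169. Among protein-coding genes alone, an alternative chosen after the data were seen, the counts were 124 for METTL14, 75 for WTAP and 49 for ALKBH5.

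Few genes separated the writers from the erasers. Both eraser IPs lay at least 2-fold above all 3 writer IPs for 64 genes, among them PKD1, the polycystin-1 gene (log2 gap 1.73, chromosome 16, 2088708 to 2135898), SLC12A4, a potassium-chloride cotransporter (1.43), and NBPF12 (1.28). PKD1 and NBPF12 could share reads with near-identical copies, so their values are uncertain. The 3 writer IPs lay above both eraser IPs for 31 genes, of which ZCCHC10 (1.12), PTTG1, the securin of sister chromatids (1.07), and RPL9P9 (1.02), a pseudogene, were named by the rule. PTTG1 was below INPUT in the METTL14 and WTAP IPs too, at -1.20 and -1.17, and at -2.33 and -2.27 in the eraser IPs. The other 9 splits of the IPs into 3 and 2 gave 43 to 224 genes in all, against 95 for writers and erasers. With plain totals 19 genes were higher in the writers. The 224 came from setting METTL14 and FTO, the shallow libraries, against the other 3.

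Correlations between the methyltransferase subunits were compared with those of the other pairs. Across 14029 genes, which are not independent replicates, the Spearman correlation of log2 ratios was 0.34 for METTL3 and METTL14, 0.30 for METTL3 and WTAP, and 0.47 for METTL14 and WTAP. It was 0.64 for WTAP and ALKBH5, 0.61 for ALKBH5 and FTO, 0.57 for METTL14 and ALKBH5, 0.49 for METTL14 and FTO, 0.44 for METTL3 and ALKBH5, 0.41 for METTL3 and FTO, and 0.43 for WTAP and FTO. Because every ratio shares the INPUT, draws with no effect gave, for these 10 pairs in turn, 0.36, 0.53, 0.35, 0.49, 0.36, 0.34, 0.26, 0.51, 0.38 and 0.37. The METTL3 pairs with METTL14, WTAP and ALKBH5 lay below their draws. The draws hold counting error alone, so their correlations are no lower limit for real profiles and these pairs cannot be called less alike than with no effect. The covariance was 0.32 to 0.78 over the 10 pairs, against 0.0148 to 0.0161 in the draws. WTAP and ALKBH5 shared 651 higher and 1331 lower genes, where independent lists would share 224 and 351, and METTL3 and WTAP shared 105 and 337, against 44.8 and 121. Part of this excess may come from the single INPUT.

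By biotype, lncRNA genes had medians of -0.46, -0.57, 0.02, -0.50 and -0.21 over 482 genes, in the order METTL3, METTL14, WTAP, ALKBH5 and FTO, against -0.05 to 0.06 for 11732 protein-coding genes. Pseudogenes were higher for 196 of 644 genes in the WTAP IP and lower for 262 in the ALKBH5 IP, with reads that parent genes could share. The genomic span of protein-coding genes, which includes introns, had Spearman correlations across genes of -0.10 with the METTL3 ratio and 0.24, 0.22, 0.34 and 0.14 with the METTL14, WTAP, ALKBH5 and FTO ratios.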

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

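The tests below of the splits, the regulators' own transcripts, the cytoskeletal families and the kinase genes were chosen only after the results were seen. Among the 217 named genes, 4 had counting intervals on one side of INPUT in the 3 writer IPs and on the other side in both eraser IPs, and this difference between the groups was not tested. The mean log2 ratio of the writers minus that of the erasers was 1.17 for ALDH1A1, a retinal dehydrogenase, 0.878 for ATP5A1 and 1.01 for ATP5B, subunits of ATP synthase, and -1.53 for SLC12A4. In the split of the 5 IPs into writers and erasers 95 genes separated the groups, 6 of the 10 possible splits gave as many, and the highest other split gave 224. With 10 splits no share under 0.05 can be reached. The split with 224 genes sets both shallow libraries against the rest, and gave 210 on libraries thinned to the smallest total, a count chosen after the data were seen, where writers against erasers gave 94.

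The 5 regulator transcripts were each highest in their own IP, by log2 0.45 over the next IP for METTL3 (95% counting interval 0.36 to 0.55), 0.87 for METTL14 (0.76 to 0.98) and 0.63 for WTAP (0.57 to 0.70). For ALKBH5 (0.05, -0.03 to 0.13) and FTO (0.00, -0.10 to 0.10) the next IP was not separable by counting error. Over the 120 ways to pair antibodies and transcripts the exact one-sided p was 0.00833, the smallest they can give, and the mean deviation lay at percentile 99.8 of random sets of genes of similar abundance (98.8 to 99.8 with any 1 transcript left out). Both follow from the pattern that was seen first and decide nothing about chance pairing or ordinary spread, and singly METTL3 (84.9), FTO (89.9) and ALKBH5 (62.4) lay within that spread while METTL14 (99.1) and WTAP (97.9) carried the mean. Capture of ribosomes through the nascent regulator protein may be a cause, a hypothesis with no test here, since no IgG pulldown or translation inhibitor was among the libraries.

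In the METTL14 IP, 10 of 11 tubulin genes and 28 of 36 genes of actin-binding families, groups chosen after their values were seen, were higher than INPUT, with medians of 2.19 and 2.10. The tubulins had medians between -0.93 and 0.15 in the other 4 IPs, but the actin-binding families were also higher for 30 genes in the ALKBH5 IP and 21 in the FTO IP, each with a median above all 10000 random lists. The 8 tubulin genes of short genomic span (at most 11233 bases, which transcript length cannot exceed) had a METTL14 IP median of 2.20. Their lower quartile was 1.85, against medians of -0.24 for other short genes and 0.31 for the genes of longest span. For these 8 genes, the values argue against a preference for long transcripts as the cause. They come from 1 library and from genes chosen for high METTL14 values. For the actin-binding families such a preference cannot be told apart. Their METTL14 minus ALKBH5 median was 0.63, against -0.60 for other very long mRNAs (percentile 100). This comparison, too, used genes chosen for high METTL14 values. Medians were at least 2-fold above INPUT in 6 of 6 families, more than reads shared within the family of 1 abundant gene would give. Sharing within each family was not tested. Cytoskeletal protein complexes held by this antibody may be a cause, on which the median of 0.956 (log2) over the highest other IP decides nothing without an IgG pulldown, and regulation by METTL14 was not tested.

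Several kinase genes that INPUT and 3 IPs barely showed had many reads in the WTAP and FTO IPs. RET had 286 and 334 reads there and at most 16 elsewhere, and ALK, which stood out in the WTAP IP more than in the FTO IP, 1545 and 68 against at most 24. In all, 14 genes were at least 4-fold above every other library in both IPs, against 48 for METTL14 with FTO and 0 for the other 8 pairs. No CPM minimum was applied, and a comparison library was taken to hold at least 3 reads, a higher floor in the shallow libraries. Only METTL14 with FTO was set against deep libraries alone, so its 48 genes met a lower bar. Outside neural cells, 14 markers of other cell types were silent in INPUT (under 1 CPM) and had at most 11 reads in either IP. The 11 were of PECAM1 in the FTO IP, where PTPRC had 5, while KIT had at least 599 in both IPs. CD14 and COL1A1 were not silent in INPUT and were left out. The counts would argue against blood, immune, endothelial or fibroblast cells as the source of the KIT reads only under 1 condition. The antibodies would have to capture marker RNAs as they did KIT, which was not tested. On their few reads, PECAM1 and PTPRC in the FTO IP lay log2 1.21 and 1.79 above every library but the WTAP IP. RNA of liver, islet, heart or neural cells stays open, with 1 silent marker each (at most 10 reads of GFAP for neural cells). Material from a set of cancer genes outside these cells could be a source: 3 of 24 silent receptor tyrosine kinases rose in both IPs, against 10 of 18459 other silent genes, but the family was chosen because it shows the pattern, so this cannot be told apart from a property of the RNAs.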

How the results depend on the processing

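No paired analysis or left-out replicate was possible, because each group holds 1 library. Counts of protein-coding genes alone and counts without the METTL14 and FTO IPs were chosen after seeing the data. All 19 gene counts stayed within 1.5 times with DESeq2 size factors, with libraries thinned to the smallest, and with dominant genes removed. List medians moved by less than their spread in 119 of 120 cases with DESeq2 size factors and in 102 with plain totals, and of 531 called ratios of named genes 523 and 500 were still called under these scalings. The mitochondrial, small structured and snoRNA lists gave no value once dominant genes were removed, and the snoRNA list gave none with a mean CPM of at least 5. The depth of the METTL14 and FTO IPs limits calls among rare transcripts there. Where no cause is given below, the cause was not tested.

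With plain totals, 798 genes were higher in the METTL3 IP, the IP-specific counts were 479 (METTL3), 146 (METTL14) and 169 (WTAP), 19 genes were higher in the writers, and the METTL3 medians of ZNF and oxidative phosphorylation genes turned to 0.0346 and 0.0220. With 5 reads added, 14 genes were higher in the writers.

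With a mean CPM of at least 5, which leaves fewer genes, 260 genes were higher and 346 lower in the METTL3 IP, 973 and 1090 in the METTL14 IP, and 1217 and 1281 in the FTO IP. In all 5 IPs 13 were higher and 101 lower, 63, 103, 38 and 274 were specific to METTL14, WTAP, ALKBH5 and FTO, and 7 and 35 were higher in writers and in erasers. With no filter, which adds genes of few reads, 651 were higher and 2376 lower in the METTL3 IP, 3215 higher in the METTL14 IP, 2414 higher in the WTAP IP, 4023 lower in the ALKBH5 IP, and 3169 and 2968 in the FTO IP. In all 5 IPs 272 were lower, 1308, 730, 228 and 1305 were specific to METTL14, WTAP, ALKBH5 and FTO, and 154 and 149 separated writers and erasers.

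With the interval itself past 2-fold, a stricter rule by construction, 145 were higher and 543 lower in the METTL3 IP, 891 and 963 in the METTL14 IP, 997 higher in the WTAP IP, and 1126 and 1134 in the FTO IP. In all 5 IPs 4 were higher, 140, 80, 126, 20 and 249 were specific to METTL3, METTL14, WTAP, ALKBH5 and FTO, and 2 and 12 were higher in writers and in erasers. Among protein-coding genes, 326 were lower in the METTL3 IP, 1022 higher in the WTAP IP, 18 higher and 80 lower in all 5, 124, 75 and 49 specific to METTL14, WTAP and ALKBH5, and 8 higher in the writers. Without the METTL14 and FTO IPs, fewer libraries have to meet the rule, and 66 were higher and 301 lower in the other 3.

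Against the other 4 IPs in place of INPUT, which asks how an IP differs from the rest, 1141 genes were higher in the METTL3 IP, 1005 higher and 1223 lower in METTL14, 890 lower in WTAP, 751 higher and 1290 lower in ALKBH5, and 731 lower in FTO. List medians outside the central 95% of random lists against INPUT that changed sign were small structured RNAs (METTL14 2.70, FTO 2.15), mitochondrial RNAs (METTL14 1.78, FTO 2.50), ribosomal proteins (METTL3 0.65, METTL14 0.44, WTAP 0.0239), histones (METTL14 1.37, FTO 1.03), ZNF genes (METTL14 -0.0319), oxidative phosphorylation (METTL3 1.20, METTL14 0.26), immediate early genes (METTL3 -0.25), very long mRNAs (METTL3 -1.40, WTAP -0.43) and 5'TOP mRNAs (METTL3 0.21, METTL14 0.17).

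Ratios to the mean of the 5 IPs push correlations below 0 by construction. Their mean was -0.227, with -0.206 for METTL3 and METTL14, -0.202 for METTL3 and WTAP, -0.403 for METTL3 and ALKBH5, -0.157 for METTL3 and FTO, -0.231 for METTL14 and WTAP, -0.240 for METTL14 and ALKBH5, -0.228 for METTL14 and FTO, -0.00659 for WTAP and ALKBH5, -0.431 for WTAP and FTO, and -0.160 for ALKBH5 and FTO.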

Other observations

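The grouping of mitochondrial genes by strand in this part was chosen only after the values were seen. Genes encoded on the light strand of mitochondrial DNA, MT-ND6 and several tRNA genes, had group medians above INPUT in 4 of the 5 IPs, unlike other mitochondrial RNAs. Members differed: MT-ND6, which had the most INPUT reads (4445), was above INPUT only in the METTL3 (0.34) and FTO (0.91) IPs. MT-TE had log2 ratios below 0 in all 5 (-2.35 to -0.40). The 7 measured light-strand genes had medians of 1.44 in the METTL3 IP, 0.54 in the METTL14 IP, -0.66 in the WTAP IP, 0.76 in the ALKBH5 IP and 1.58 in the FTO IP, and 4, 2, 0, 3 and 4 of them were higher and 0, 1, 2, 0 and 0 lower. The 14 measured mRNAs and ribosomal RNAs of the heavy strand had medians of -5.50, -1.78, -4.68, -4.23 and -1.26, and of 12 measured heavy-strand tRNA genes 12 were lower in each of the 5 IPs. The strand setting of the counting is not known, so reads counted for a light-strand gene were not told apart from reads of the opposite strand.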
